A study of Mus musculus with 8 samples.

How the data were processed

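Polyadenylated RNA was sequenced from the livers of wild-type C57/BL6 mice at 8 circadian times (CT), 6 h apart, from CT23 to CT65. Per the labels' protocols, the animals had spent a week in alternating light and darkness and were moved to constant darkness a day ahead of the collection, so that CT counts hours of the internal day. RNA of 3 animals was combined in equal parts into 1 pool, and 1 library was made per time. The labels give neither sex nor age. The 8 times cover 2 internal days, so each clock phase was sampled on both: CT23 and CT47 (called CT23 here, the end of the subjective night), CT29 and CT53 (CT5, the middle of the subjective day), CT35 and CT59 (CT11, the end of the subjective day), and CT41 and CT65 (CT17, the middle of the subjective night). No time has a replicate library.

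Reads had been aligned to mm9, per the submitters' processing notes, and all coordinates are in that build. The deposited transcript tables list, for each annotated transcript, its exons and its introns, a lower and an upper value to 4 decimals. Per the file headers these values are named only min and max. They scale as reads per length of the feature and depth of the library (RPKM), and what separates the lower from the upper one is not given in the sources used here. The quantifying program is not named there either. The deposited junction tables hold the count of reads across each splice junction, as whole numbers not scaled for depth, and their track lines name high-quality junctions from RUM, per the file headers. The RUM version, the read length, the thresholds behind the junctions and the strand setting of the quantification are not given in the sources used here. Reads from genes that overlap on opposite strands, and reads shared by paralogs, can therefore not be separated.

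The lower value of every transcript was a whole multiple of 1 step that depended on its length and its library, within 0.1 read for 99.87 to 99.94% of transcripts per library. This gave the number of reads behind each value and the number of reads that 1 RPKM stood for. The lower value was used throughout, and the upper one served as an alternative. Of 115699 transcripts, 79709 (68.89%) carried a gene name, 25898 of them through RefSeq and 53811 through Vega identifiers matched to the GRCm38.p6 annotation, which was used for names and GC content and for no coordinates. They named 24143 genes. Each gene was represented by the transcript with the most reads over all libraries. Older symbols of the same gene were merged after a first round of calls had been seen, because some genes had been counted under an old and a new symbol.

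The test planned for counts was edgeR's quasi-likelihood test. Because the tables hold RPKM, the test planned for that case was used instead: limma with a mean trend and robust variances on log2(RPKM + 0.5), for genes with at least 20 recovered reads in at least 2 libraries. Fold changes are on that scale, which understates changes of weakly expressed genes. Each gene was fitted with a cosine and a sine of 24 h with the origin at CT23, which leaves 5 residual degrees of freedom. The joint test of both terms gave the 24-h component. The cosine alone compared CT23 with CT11, and the sine alone compared CT5 with CT17. The 12-h component set CT23 and CT11 against CT5 and CT17 beside the 24-h terms (4 residual degrees of freedom), and the second day was compared with the first with the clock phase as a block (3 residual degrees of freedom). P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and an adjusted p under 0.05 is called. The p-values measure the spread of single pooled libraries around the fitted curve, in which pool, lane and day are joined, and not the spread between animals. The peak-to-trough fold and the peak time were taken from the fitted curve, each with its standard error (SE).

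A total of 40 gene lists were tested for 24-h calls with 1-sided Fisher's exact tests against all other genes tested, and with camera on the cosine and on the sine, with a preset correlation of 0.01 (76 tests). Camera was run on the log2 values with a variance trend in place of the planned voom weights. The lists were drawn up from general knowledge of liver. Several share members, and most markers of other cell types are also expressed at some level in hepatocytes. The lists, the tests and thresholds, the alternatives and the genes to be named were chosen before the data were examined, except where stated. Named were all measured clock genes. To these were added the 5 called genes of largest amplitude per nearest sampled peak phase, with a mean of at least 5 RPM and the same direction on both days. For the 12-h component and the days it was the 5 largest changes each way. For each list it was up to 4 called members of smallest adjusted p and up to 2 of highest mean that were not called. For introns it was the clock genes and the 3 largest lags each way, and for junctions the 5 smallest adjusted p and Upp2, the measured one of 6 genes named in advance. A few genes that these rules take are not reported here.

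Intron reads were summed over the introns of the chosen transcript that overlap no exon of another transcript (149366 of 184181 introns), for genes with a mean of at least 20 intron reads per library. They were tested with limma on log2(intron RPM + 0.5), with reads scaled to the sum of a library's intron reads, where edgeR had been planned. For genes called in exons and in introns the lag is the exon peak time minus the intron peak time. Junction usage was the share of a junction among the junctions with which it shares a splice site, tested with a quasi-binomial regression on the 24-h terms where at least 20 competing reads were present in every library and the mean share was 5 to 95%.

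Alternatives were edgeR (with TMM or median-of-ratios factors), DESeq2 and limma-voom on the recovered reads, pseudocounts of 0.1 and 1, no low-read filter, a mean of at least 100 reads, the upper values, the longest transcript, thinning to the shallowest library, the day as a block, the clock phase as a factor, and leaving out each library in turn. Counts by edgeR are those with TMM unless stated. Chosen after seeing the data were edgeR with TMM as an alternative, rescaling the RPKM by TMM factors or to equal medians, removal of each library's trend on GC content and length (loess, span 0.5; both known for 98.7% of tested and 98.6% of called genes), array weights, and the lists and introns without CT35. For the lists, CT35 was the one library left out.

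The 24-h, 12-h and day tests were tried on simulated counts with the real means and library sizes and a dispersion of 0.02, with 200 of 11483 genes changed. The single contrasts between phases and the list tests were not simulated. For the 24-h component, limma recovered 45.5% of genes with a peak-to-trough log2 change of 1 and 98.5% with one of 2, and edgeR recovered 61% and 99.5%. For the 12-h component and for the days, limma recovered 94% at a log2 change of 1. Every simulated gene had the same dispersion, and the wider spread of the CT35 library was not included. Recovery in the real data may therefore be lower than these shares. In introns 46% were recovered at a log2 change of 1 and 100% at 2, among 6528 genes with 200 changed, and a simulated lag of 2 h was returned as 1.98 and 2.05 h. For junction usage, with an overdispersion of 0.002, none of 200 changed events among 1500 was recovered at a log-odds change of 1, and 43.5% at 2. With no simulated change, no call was made in the 24-h, intron and junction tests. With 200 changed, false calls by limma numbered 5 and 15 for the 24-h component at log2 changes of 1 and 2, where edgeR made 8 and 12. They numbered 13 for the 12-h component, 19 for the days, and 5 and 8 in introns, and the quasi-binomial test made 0 and 8 in junctions. Software was R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and bedtools 2.31.1.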

Results

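The 8 libraries sampled the liver transcriptome of mice in constant darkness over 2 internal days, with 1 library of 3 pooled animals at each of CT23, CT29, CT35, CT41, CT47, CT53, CT59 and CT65. Reads behind 1 RPKM numbered 11.7 to 13.9 M (mega) in 7 libraries and 22.9 M in CT35. Reads assigned to named genes numbered 7.76 to 8.92 M in the 7 and 16.8 M in CT35, and 15670 to 16586 genes had at least 1 read. Alb, which encodes serum albumin, averaged 35070 RPKM. The 10 most abundant genes held 19.6 to 23.6% of gene reads in the 7 libraries and 26.1% in CT35. The CT35 library also stood apart in its share of intron reads (7.87% against 11.9 to 13.8%), in its junction reads per 100 reads (64.5 against 41.4 to 49.5) and in its median correlation with the other libraries (0.930 against 0.959 to 0.969). Libraries of the same clock phase correlated at 0.979 for CT23 and CT47, 0.980 for CT29 and CT53 and 0.978 for CT41 and CT65, and at 0.951 for CT35 and CT59.

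**Figure D1:**
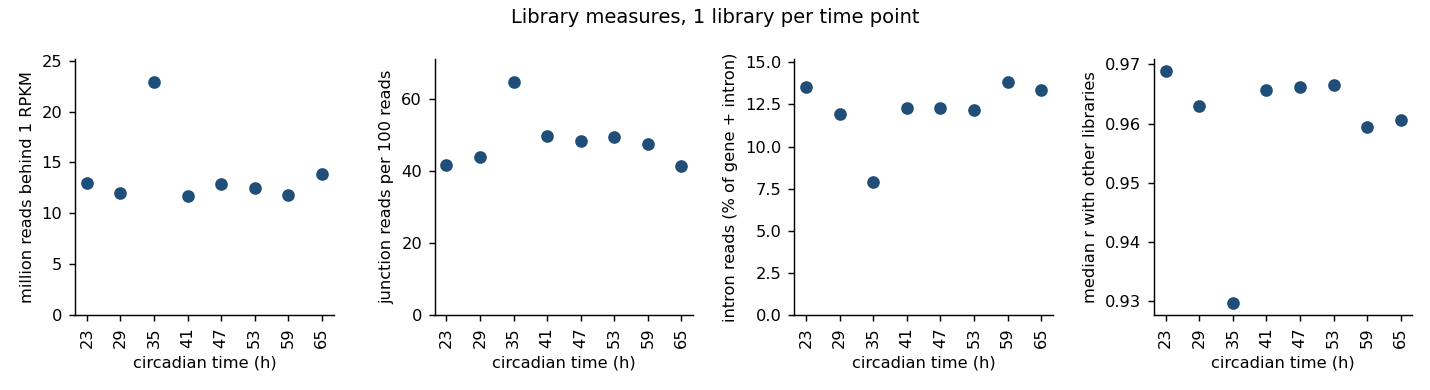
Depth and composition of the 8 libraries by circadian time in hours: reads behind 1 RPKM, junction reads per 100 reads, percent of reads in introns, and the median Pearson correlation with the other libraries on an axis that does not start at 0; each point is 1 library. CT35 lies apart in each panel, at 22.9 M reads, 64.5 junction reads per 100 reads, 7.87% intron reads and a median correlation of 0.930.

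The first question was which transcripts rose and fell with a 24-h period. The largest rhythm was that of Dbp, a transcription factor under direct control of the clock, which peaked at circadian time 9.15 h (SE 0.21) and differed 90.6-fold between peak and trough (log2 6.5, SE 0.35, adjusted p = 7.39e-06). Dbp lies on chromosome 7 from 52960458 to 52965525 in mm9 and shares 27.4% of its exon bases with Sphk2 on the opposite strand. Near the end of the subjective night the largest amplitudes were those of Pitx3, a homeobox factor (20.8-fold, peak at 21.38 h), Arntl, the core activator of the clock (15.9-fold, 21.63 h), and Elovl3, a fatty acid elongase (13.8-fold, 22.62 h). They were followed by Tubb2a, a beta-tubulin (12.0-fold, 22.43 h), and Cdkn1a, the cell cycle inhibitor p21 (10.5-fold, 21.41 h). Pitx3 lies beside Elovl3 on chromosome 19 and shares 0.7% of its exon bases with it, and no read spliced across the introns between the exons of Pitx3 next to Elovl3 was seen.

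In the middle of the subjective day the largest were Nr1d1, which encodes the repressor REV-ERB alpha (40.7-fold, 6.65 h), Clec2h, a C-type lectin (7.52-fold, 7.10 h), and Thra, a thyroid hormone receptor (6.99-fold, 5.32 h). Next were Mt1, a metallothionein (5.70-fold, 7.70 h), and Syt1, a synaptotagmin (4.84-fold, 7.38 h). Thra and Nr1d1 overlap on opposite strands, and in the exons of Thra that overlap no other gene the log2 peak to trough was 0.72 (adjusted p = 0.45) against 2.81 over the whole gene. Near the end of the subjective day Dbp was followed by Rgs16, a regulator of G-protein signalling (21.8-fold, 8.74 h), Ciart, a repressor within the clock (16.1-fold, 10.92 h), Mfsd2a, a lysophosphatidylcholine transporter (14.4-fold, 10.80 h), and Lpin1, a phosphatidate phosphatase (13.9-fold, 10.98 h). In the middle of the subjective night they were Clic3, a chloride channel protein (10.9-fold, 19.60 h), and Saa2 and Saa1, serum amyloid A proteins of the acute phase (9.68-fold at 16.84 h and 6.38-fold at 16.35 h). Next were Per2, a repressor within the clock (6.66-fold, 14.70 h), and H3c14, a histone H3 gene (5.45-fold, 18.73 h). Saa1 and Saa2 are close paralogs, so reads may be shared between them. Over these genes the SE of the log2 peak to trough was at most 0.66 (Nr1d1), and the adjusted p ran from 7.39e-06 (Dbp and Pitx3) to 0.0164 (Mt1). The Nr1d1 call was lost without CT29 or CT65 (adjusted p up to 0.0746), that of Mt1 without CT35, CT53 or CT65 (up to 0.072) and that of Mfsd2a without CT35 (0.155).

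Of 11483 genes tested with limma, 349 (3.04%) had a 24-h component, and 1949 had an unadjusted p under 0.05. The median peak-to-trough fold of the called genes was 2.64. It was at least 2 in 318 genes and at least 4 in 65. The nearest sampled peak was CT23 for 111 genes, CT5 for 93, CT11 for 89 and CT17 for 56. The order of CT5 and CT17 rested on scaling, with 55 and 81 after TMM rescaling, 48 and 92 with equal medians and 69 and 105 with edgeR. CT23 led in these settings (109, 114 and 126), but CT5 led without CT35 (158 against 117) and without CT59 (52 against 44), and CT11 with array weights (295 against 237). The number of calls was 179 without CT23, 196 without CT41, 187 without CT53 and 177 without CT59, and 96 genes were called whichever library was left out. It was 768 with DESeq2, 334 of them among the 349, 894 with array weights and 89 without a low-read filter.

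**Figure D2:**
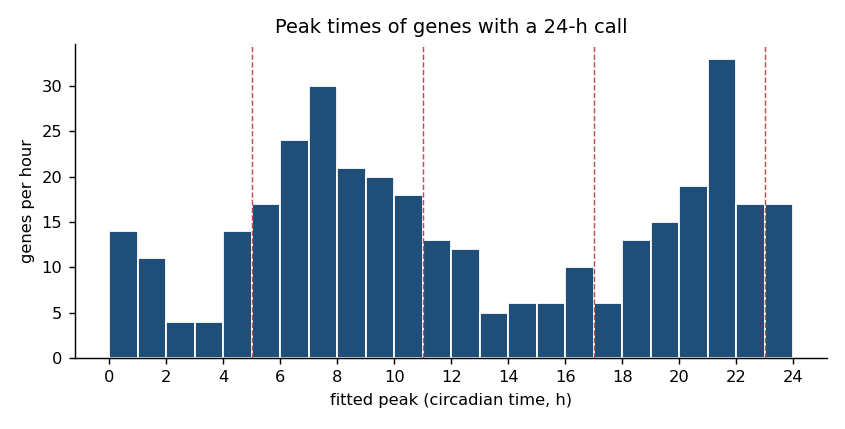
Fitted peak times of the 349 genes with a 24-h component, in bins of 1 h; the horizontal axis is circadian time in hours, the vertical axis the number of genes, and dashed lines mark the sampled phases CT5, CT11, CT17 and CT23. With the RPKM as given 111 peaks lay nearest to CT23 and 56 to CT17, against 109 and 81 after TMM rescaling.

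Of 25 measured clock genes, 16 were called and 19 when adjusted over the list alone, and the list held more 24-h calls than the other genes tested (adjusted p = 2.34e-17, Fisher's exact test). The activators Arntl (chromosome 7, 120350979 to 120457636), Npas2 (9.91-fold, 23.42 h) and Clock (2.59-fold, 0.07 h) peaked around the end of the night. The repressor genes Bhlhe41 (3.07-fold, 6.47 h), Nr1d1 and Nr1d2, which encodes REV-ERB beta (8.23-fold, 8.58 h), peaked during the day. Genes of the repressor arm and of D-box factors peaked toward the end of the day and in the early night: Tef (5.93-fold, 10.91 h), Per1 (6.30-fold, 11.12 h), Per3 (9.13-fold, 11.50 h), the deubiquitinase Usp2 (7.21-fold, 12.74 h) and Per2. Cry1, a repressor (3.89-fold, 18.51 h), and Nfil3, the repressor at D-boxes (4.68-fold, 20.41 h), peaked later in the night. Over the called clock genes the adjusted p ran from 7.39e-06 for Dbp to 0.04 for Npas2, and the SE of the peak time from 0.21 h for Dbp to 0.75 h for Clock. Not called were Cry2 (2.20-fold, adjusted p = 0.0546), Bhlhe40 (0.133), Timeless (0.506), Hlf (0.67), Fbxl21 (0.67), Rora (0.792), Csnk1e (0.898) and Csnk1d (0.917). The call of Npas2 was lost without CT23, CT29, CT35, CT47 or CT65 (adjusted p up to 0.18), and that of Per1 without CT23, CT29, CT47, CT59 or CT65 (up to 0.107). That of Clock was lost without CT23, CT35, CT41, CT53 or CT59 (up to 0.152), that of Bhlhe41 without CT53 (0.052) and that of Nr1d1 without CT29 or CT65 (up to 0.0746).

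**Figure D3:**
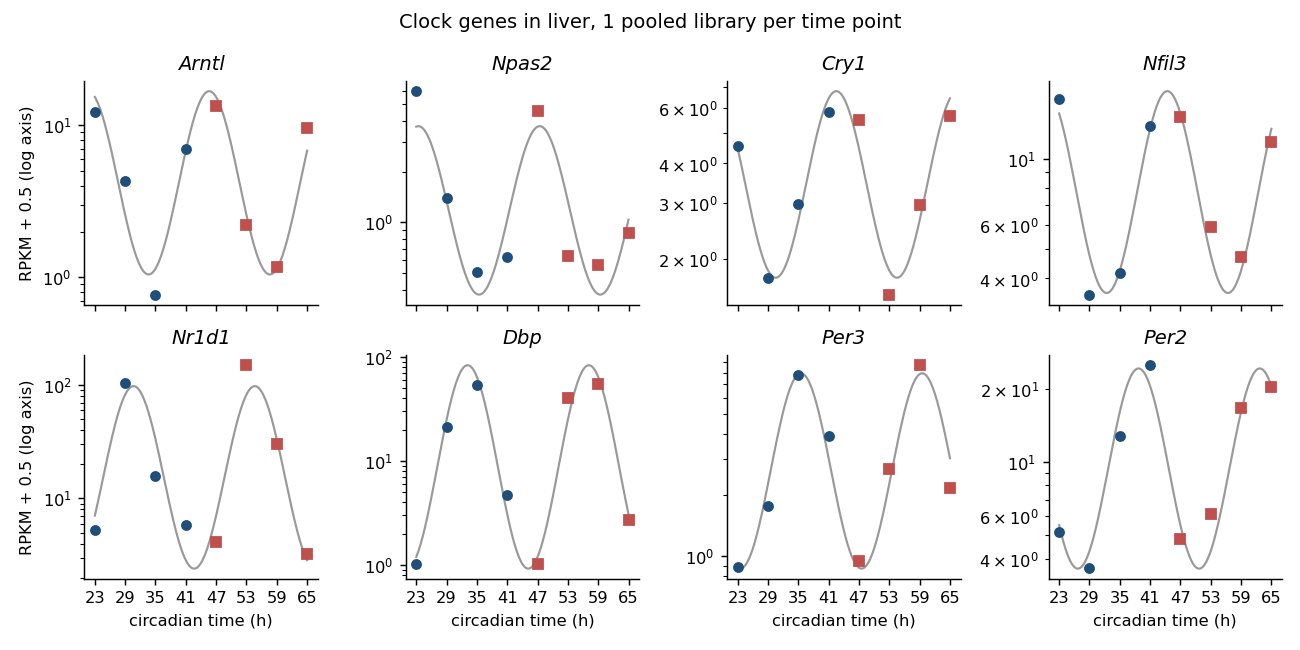
Expression of 8 clock genes, including Arntl, Nr1d1, Dbp and Per2, against circadian time in hours; the vertical axis is RPKM + 0.5 on a log scale, circles are libraries of the first day, squares those of the second day, and grey lines are the fitted 24-h curves. Dbp spans the widest range (90.6-fold between fitted peak and trough), and Arntl peaks at 21.63 h against 6.65 h for Nr1d1.

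Genes known as targets of REV-ERB and ROR factors through RORE sites were called in 7 of 9 measured members, and in 8 when adjusted over the list alone (adjusted p = 1e-08, Fisher's exact test). Among them were Cry1, Nfil3, Arntl, Npas2 and Clock, with peaks from 18.51 h to 0.07 h, and Elovl5, an elongase of polyunsaturated fatty acids (2.67-fold, 1.32 h, adjusted p = 0.0231), and Gsk3b (0.74) and E2f8 (0.148) were not called. All of the called members but Elovl5 are also on the list of clock genes. The list was drawn up from genes with a night peak in other liver studies. Its calls and its direction between CT23 and CT11 could therefore be foreseen. The list was higher at CT23 than at CT11 by camera (adjusted p = 2.32e-09, and adjusted p = 0.0939 with an estimated correlation). Between CT5 and CT17 camera called it lower at CT5 (adjusted p = 0.0029, and 0.224 with an estimated correlation) although its median log2 difference was 0.10 and its mean −0.56, and the median was −0.02 after TMM rescaling. Without CT35, 5 members were called, and the call of Elovl5 was lost without CT47, CT53 or CT59 (adjusted p up to 0.0863). Of the targets of E-boxes and D-boxes 13 of 18 were called, 17 when adjusted over the list alone (adjusted p = 2.2e-15), and the list was lower at CT23 than at CT11 with a median log2 difference of −1.77 (camera adjusted p = 3.24e-24, and adjusted p = 0.122 with an estimated correlation). Its highest-mean members not called were Por, the electron donor of P450 enzymes (2.93-fold, adjusted p = 0.0578), and Bhlhe40. All of its called members but Wee1 and Nampt are also on the list of clock genes. It was drawn up from genes with a day to dusk peak in other liver studies, so its calls and direction could likewise be foreseen. The list of all clock genes was also lower at CT23 than at CT11 (camera adjusted p = 0.000502, and adjusted p = 0.514 with an estimated correlation). Over all lists camera made 18 calls, of which 0 held with an estimated correlation, and apart from the RORE list between CT5 and CT17 no list it called had a median that changed sign with the scaling.

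The end of the subjective night was compared with the end of the subjective day. Higher at CT23 than at CT11 were Pitx3 (log2 3.99, SE 0.25, adjusted p = 5.54e-06), Elovl3 (3.77, SE 0.30), Arntl (3.74, SE 0.37), Tubb2a (3.55, SE 0.39), and Cdkn1a (3.11, SE 0.32). Also higher was Ppp1r3c, a glycogen-targeting subunit of protein phosphatase (2.44, SE 0.24). Reads counted for Pitx3 may come from the neighbouring Elovl3, since none was spliced between its exons next to that gene. Lower at CT23 were Dbp (−5.75, SE 0.35, adjusted p = 5.54e-06), Ciart (−4.01, SE 0.31), Mfsd2a (−3.84, SE 0.55), Lpin1 (−3.80, SE 0.41), Rgs16 (−3.70, SE 0.31), and Per3 (−3.16, SE 0.28). Also lower were Pck1, the gluconeogenic enzyme PEPCK (−2.17, SE 0.32), and Fkbp5, a glucocorticoid-induced chaperone (−2.06, SE 0.27). Between these phases 234 genes differed, 127 higher and 107 lower at CT23, and 1590 had an unadjusted p under 0.05. The number was 105 without CT23, 137 without CT47, 72 without CT59, 57 without a low-read filter, 486 with DESeq2 and 708 with array weights, where 311 were higher and 397 lower. Among the genes named the call of Mfsd2a was lost without CT35 (adjusted p = 0.155).

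The middle of the subjective day was then compared with the middle of the subjective night. Higher at CT5 than at CT17 were Nr1d1 (log2 4.86, SE 0.66, adjusted p = 0.00916), Dbp (3.03, SE 0.35), Thra (2.80, SE 0.39), Clec2h (2.48, SE 0.22), Rgs16 (2.48, SE 0.31), and Syt1 (1.85, SE 0.21). Also higher were Junb, a subunit of AP-1 (1.58, SE 0.26), and Klf9, a glucocorticoid-induced factor (1.49, SE 0.24). The value of Thra includes exon bases shared with Nr1d1. In its unshared exons the log2 peak to trough was 0.715 (limma adjusted p = 0.45), against 2.806 over the whole gene. Lower at CT5 were Saa2 (−3.27, SE 0.39), Clic3 (−2.67, SE 0.37), Saa1 (−2.64, SE 0.34), Per2 (−2.25, SE 0.27), H3c14 (−2.20, SE 0.31), and Cry1 (−1.81, SE 0.23). The chaperones Hsph1 (−1.72, SE 0.22) and Hsp90aa1 (−1.56, SE 0.24) were lower as well. Between these phases 138 genes differed, and 1601 had an unadjusted p under 0.05. The split between the directions rested on scaling, because the median of all genes lay 0.11 higher at CT5 on the log2 scale with the RPKM as given. At this scale 86 genes were higher and 52 lower, against 46 and 66 after TMM rescaling, 41 and 69 with equal medians and 62 and 80 with edgeR and TMM. The number of calls was 48 without CT29, 56 without CT41, 52 without CT53, 47 without CT65 and 311 without CT35. It was 294 with DESeq2 (122 higher and 172 lower), 245 with array weights (158 and 87) and 33 without a low-read filter. The calls of Nr1d1 (without CT29 or CT65, adjusted p up to 0.125), Thra (without CT29, 0.0522), Junb (without CT41, CT53 or CT65, up to 0.102), Klf9 (without CT29 or CT41, up to 0.0797) and Hsp90aa1 (without CT29 or CT65, up to 0.0574) were lost.

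Lipid synthesis held several strong rhythms. Of 24 measured genes of fatty acid and triglyceride synthesis 6 were called, and 13 when adjusted over the list alone (adjusted p = 0.000415, Fisher's exact test). They were Elovl3, Lpin1, Lpin2, a phosphatidate phosphatase (4.93-fold, 10.11 h), and Elovl5. Chosen after their values were seen were the other called members, Elovl6, another elongase (2.77-fold, 14.11 h), and Pnpla3, a lipase of lipid droplets (2.31-fold, 16.96 h). The most abundant members not called were Scd1 (adjusted p = 0.29) and Fasn (0.192). The list was lower at CT5 than at CT17, with a median of −0.31 (camera adjusted p = 1.85e-05, and adjusted p = 0.744 with an estimated correlation). The call of Lpin2 was lost without CT23 (adjusted p = 0.0553), and that of Elovl5 without CT47, CT53 or CT59 (up to 0.0863). That of Elovl6 was lost without CT23, CT29, CT41, CT47, CT53 or CT65 (up to 0.103) and that of Pnpla3 without CT29, CT41, CT47, CT53 or CT65 (up to 0.156). In cholesterol synthesis 1 of 24 genes was called, also when adjusted over the list alone (adjusted p = 0.889, Fisher's exact test). The list was lower at CT23 than at CT11 (camera adjusted p = 0.0269, and adjusted p = 0.866 with an estimated correlation), a call lost without CT35 (0.147), and its median was 0.43 higher in CT35 than in CT59. In bile acid synthesis and transport 1 of 15 was called and 4 when adjusted over the list alone (adjusted p = 0.689, Fisher's exact test). This was the hepatic uptake transporter Slco1b2 (2.19-fold, 7.27 h, adjusted p = 0.0319). Its call was lost without any library but CT35 or CT47 (adjusted p up to 0.13), and without CT35 the list had 3 calls.

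Genes of fatty acid oxidation and PPAR alpha targets had 4 calls among 23, and 5 when adjusted over the list alone (adjusted p = 0.0204, Fisher's exact test). Angptl4, an inhibitor of lipoprotein lipase (3.12-fold, 8.80 h), Cpt1a, which admits fatty acids to mitochondria (2.90-fold, 8.61 h), and Ppara itself (2.19-fold, 9.66 h) peaked late in the day, and Pdk4, which restrains pyruvate dehydrogenase (3.40-fold, 21.52 h), at the end of the night. The calls were lost without CT23 or CT59 for Angptl4 (adjusted p up to 0.0617), without CT47 or CT59 for Pdk4 (up to 0.0689), without CT23, CT53 or CT59 for Cpt1a (up to 0.0854), and without CT23, CT41, CT47, CT53, CT59 or CT65 for Ppara (up to 0.165).

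In gluconeogenesis and glycogen metabolism 5 of 15 genes were called, and 9 when adjusted over the list alone (adjusted p = 0.000415, Fisher's exact test). Pck1 peaked at 9.23 h (5.40-fold) and Gys2, the liver glycogen synthase, at 12.23 h (2.92-fold), while the glycogen-targeting subunits Ppp1r3b and Ppp1r3c peaked at 17.53 h (3.44-fold) and 21.66 h (6.03-fold). The remaining call, named after its value was seen, was Slc37a4, the glucose 6-phosphate transporter (2.59-fold, 12.27 h, adjusted p = 0.0432). Tat (2.28-fold, adjusted p = 0.0637) and Fbp1 (0.869) were not called. The list was lower at CT23 than at CT11 (camera adjusted p = 0.0098, and adjusted p = 0.744 with an estimated correlation) and lower at CT5 than at CT17 (0.0269, and adjusted p = 0.814 with an estimated correlation). In glycolysis 2 of 17 were called, 4 when adjusted over the list alone (adjusted p = 0.278). These were Pfkfb3, which makes the activator of phosphofructokinase (4.66-fold, 9.03 h), and Pklr, the liver pyruvate kinase (2.74-fold, 16.52 h), which shares 24.5% of its exon bases with Hcn3. Ldha (0.858) was not called, and the list was lower at CT5 than at CT17 (camera adjusted p = 0.0167, and adjusted p = 0.866 with an estimated correlation). The calls of Gys2 (without CT23 or CT59, adjusted p up to 0.109), Ppp1r3b (without CT53, 0.0531), Pklr (without CT29, CT41 or CT65, up to 0.109) and Slc37a4 (without any library but CT65, up to 0.141) were lost.

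NAD, one-carbon and methionine metabolism had 4 calls among 16 genes, and 5 when adjusted over the list alone (adjusted p = 0.00556, Fisher's exact test). Nampt, the rate-limiting enzyme of NAD salvage, peaked at 12.26 h (3.33-fold), Nnmt, which methylates nicotinamide, at 15.29 h (2.89-fold), and Cbs, which commits homocysteine to cysteine, at 1.94 h (2.13-fold, adjusted p = 0.0485). Mat1a (0.251) and Gnmt (0.866) were not called. The list was lower at CT5 than at CT17 (camera adjusted p = 0.0098, and adjusted p = 0.866 with an estimated correlation). The call of Nnmt was lost without CT23, CT29, CT41 or CT53 (adjusted p up to 0.0978), and that of Cbs without any library but CT35 (up to 0.166).

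Among enzymes of drug metabolism 3 of 30 were called, 5 when adjusted over the list alone (adjusted p = 0.234, Fisher's exact test). These were Fmo5, a flavin monooxygenase (2.42-fold, 17.02 h), Sult1d1, a sulfotransferase (2.15-fold, 12.36 h), and Cyp2a5, a P450 with close paralogs (3.88-fold, 12.46 h, adjusted p = 0.05). The abundant Cyp2e1 (0.366) and Cyp3a11 (0.589) were not called. The list was lower at CT5 than at CT17 (camera adjusted p = 0.00389, and adjusted p = 0.866 with an estimated correlation). The calls of Fmo5 (without CT41 or CT53, adjusted p up to 0.079), Sult1d1 (without CT23, CT47, CT53 or CT59, up to 0.103) and Cyp2a5 (without any library but CT29 or CT47, up to 0.205) were lost. Of 13 iron and heme genes 1 was called, 2 when adjusted over the list alone (adjusted p = 0.679). Slc11a2, an iron transporter (1.97-fold, 21.13 h, adjusted p = 0.0447), lost its call whichever library was left out (up to 0.12). Trf (0.986) and Hamp (0.771) were not called.

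Of 21 heat shock genes and HSF1 targets 5 were called, and 10 when adjusted over the list alone (adjusted p = 0.00191, Fisher's exact test). These were Hsph1 (3.31-fold, 17.46 h), Hsp90aa1 (3.31-fold, 18.67 h), the HSP90 cochaperone Fkbp4 (2.29-fold, 19.02 h) and the HSP70 cochaperone Bag3 (2.48-fold, 20.23 h). Named after its value was seen, Stip1, which links HSP70 and HSP90, was the remaining call (2.32-fold, 18.72 h, adjusted p = 0.05). The mean peak of the 5 was 18.8 h. Hspa8 (2.42-fold, adjusted p = 0.0679) and Hsp90ab1 (0.0951) were not called. The list was lower at CT5 than at CT17 with a median of −0.59 (camera adjusted p = 3.33e-13, and adjusted p = 0.224 with an estimated correlation), and without CT35 it had 7 calls. The calls of Fkbp4 (adjusted p up to 0.117), Bag3 (up to 0.116) and Stip1 (up to 0.194) were each lost without any library but CT35. Genes of endoplasmic reticulum stress were lower at CT5 than at CT17 as a list (camera adjusted p = 0.000138, and adjusted p = 0.623 with an estimated correlation). Of its 21 members 1 was called by limma, and 4 when adjusted over the list alone. EdgeR called 4, DESeq2 6 and voom 3. The limma call was Trib3, a pseudokinase induced by stress, which peaked in the day (4.10-fold, 7.32 h, adjusted p = 0.00892). Calr (0.185) and Hsp90b1 (0.838) were not called. Without CT35 4 members were called, and the list was then enriched in calls (adjusted p = 0.0369 against 0.846 with all libraries).

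Glucocorticoid targets had 6 calls among 15 genes, and 13 when adjusted over the list alone (adjusted p = 2.92e-05, Fisher's exact test). Cdkn1a peaked at the end of the night, Klf9 at 5.83 h (2.88-fold), Mt1 at 7.70 h, Per1 at 11.12 h and Fkbp5 at 12.11 h (4.45-fold). Zbtb16, a zinc finger repressor named after its value was seen, peaked at 11.90 h (3.09-fold). Tat and Errfi1 (adjusted p = 0.15) were not called, and the list was lower at CT23 than at CT11 (camera adjusted p = 9.71e-05, and adjusted p = 0.122 with an estimated correlation). The calls of Klf9 (without CT29 or CT41, adjusted p up to 0.0655), and Zbtb16 (without CT53 or CT59, up to 0.114) were lost, as were those of Mt1 (without CT35, CT53 or CT65, up to 0.072) and Per1 (without CT23, CT29, CT47, CT59 or CT65, up to 0.107). Of 11 immediate early genes 1 was called, 3 when adjusted over the list alone (adjusted p = 0.624, Fisher's exact test). It was Junb (3.11-fold, 5.96 h, adjusted p = 0.0123), a call lost without CT41, CT53 or CT65 (up to 0.0769). Zfp36 was not called (0.696), and without CT35 the list had 2 calls. Of 15 acute phase genes 2 were called, Saa1 and Saa2, also when adjusted over the list alone (adjusted p = 0.242), with Fga (0.21) and Fgb (0.343) not called. Of 14 cell cycle genes 2 were called, 4 when adjusted over the list alone (adjusted p = 0.234): Cdkn1a, and Wee1, a kinase that holds back mitosis (4.01-fold, 12.26 h, adjusted p = 0.003). Cdk4 (0.858) and E2f8 were not called.

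Other lists of the liver held few or no calls. Of 15 male-biased genes Elovl3 was called, also when adjusted over the list alone (adjusted p = 0.689, Fisher's exact test), with Serpina1e (adjusted p = 0.693) and Ces3a (0.753) not called. The list was higher at CT23 than at CT11 (camera adjusted p = 0.0354, and adjusted p = 0.866 with an estimated correlation). Of 5 female-biased genes (0.398) Abcd2, a peroxisomal transporter of fatty acids, was called, also when adjusted over the list alone (3.46-fold, 7.76 h, adjusted p = 0.00117). Pck1 was the call among 11 periportal genes (0.624), with 4 when adjusted over the list alone, and Cps1 (0.891) and Cyp2f2 (0.732) were not called. Among 11 pericentral genes none was called by limma, 1 when adjusted over the list alone, 2 at an unadjusted p under 0.05, 0 with edgeR or voom, 1 with DESeq2 and 2 without CT35; the most abundant were Cyp2e1 and Cyp1a2 (0.749). Urea cycle and amino acid breakdown had 0 calls among 18, also when adjusted over the list alone (6 at an unadjusted p under 0.05, 0 with edgeR or voom, 5 with DESeq2), with Cps1 and Hpd (0.557) its most abundant genes. Secreted hepatocyte proteins had 0 among 17 by each tool, adjusted over the list alone and at an unadjusted p under 0.05, with Alb at 0.619 and Serpina1e at 0.693. For lists with no call Fisher's exact test gave an adjusted p of 1, here and in the lists that follow.

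Genes of basic cell functions had 0 calls by limma, edgeR and voom, and 0 adjusted over the list alone. At an unadjusted p under 0.05 stood 3 of 30 ribosomal protein genes, 2 of 18 ribosome biogenesis genes, 1 of 27 proteasome genes, 1 of 23 oxidative phosphorylation genes and 1 of 15 reference genes, and DESeq2 called 1 in each list but oxidative phosphorylation, where it called 0. Their most abundant members were Rpl4 (adjusted p = 0.772), Rplp0 (0.76), Ncl (0.265), Npm1 (0.397), Psmd1 (0.822), Psmd3 (0.415), Atp5b (0.957), Atp5a1 (0.619), Eef1a1 (0.773) and B2m (0.61). Medians in CT35 exceeded those in CT59 by a log2 difference of 0.80 for ribosomal proteins, 0.58 for oxidative phosphorylation, 0.52 for secreted proteins and 0.50 for the proteasome. Oxidative phosphorylation was lower at CT23 than at CT11 (camera adjusted p = 0.0269, and adjusted p = 0.932 with an estimated correlation), a call lost without CT35 (0.843). The 6 cold-inducible RNA-binding protein genes had 0 calls by each tool, 2 adjusted over the list alone and 2 at an unadjusted p under 0.05, with Srsf5 (0.486) and Srsf2 (0.8) the most abundant, and no mitochondrially encoded gene was among the genes tested.

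Lists of other cells held at most 1 call each. Of 6 cholangiocyte genes (adjusted p = 0.439, Fisher's exact test) Sox9, a transcription factor of bile duct cells, was called, also when adjusted over the list alone (3.26-fold, 21.49 h, adjusted p = 0.031). The call was lost without CT23, CT29, CT35 or CT53 (adjusted p up to 0.123). Krt18 was not called (0.823), and the list's median was 1.02 higher in CT35 than in CT59. Of 8 lymphocyte genes 1 was called, and 2 when adjusted over the list alone (adjusted p = 0.534, Fisher's exact test), with Cd74 not called (0.422). The list was higher at CT5 than at CT17 (camera adjusted p = 0.0098, and adjusted p = 0.514 with an estimated correlation). Of 5 erythroid genes none was called by limma, 3 when adjusted over the list alone and at an unadjusted p under 0.05, 1 by edgeR, 2 by DESeq2 and 1 by voom. Its most abundant members were Hbb-bs (1.81-fold, adjusted p = 0.165) and Alas2 (0.878). The list was higher at CT23 than at CT11 (camera adjusted p = 0.0098, and adjusted p = 0.744 with an estimated correlation). Limma, edgeR and voom called 0 of 13 Kupffer cell genes (1 adjusted over the list alone, 2 at an unadjusted p under 0.05, 1 with DESeq2 and 1 without CT35; C1qb 0.821, Clec4f 0.82). For the next 5 lists limma, edgeR, DESeq2, voom and adjustment over the list alone gave 0 calls each. They were 12 endothelial genes (1 at an unadjusted p under 0.05; Eng 0.855), 12 stellate cell genes (0; Ecm1 0.324, Dcn 0.831), 3 adipose genes (1; Lipe 0.585, Cidec 0.27), 4 X inactivation and Y-linked genes (1; Eif2s3y 0.764, Ddx3y 0.293) and 1 pancreas gene, Cela1 (0; 0.731), which was called without CT35.

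A 12-h component sets CT23 and CT11 apart from CT5 and CT17. The 1 gene called was Lcn2, which encodes the iron-scavenging acute phase protein lipocalin. It stood at 7.38, 15.4, 6.61 and 16.7 RPKM at CT29, CT41, CT53 and CT65 and at 4.30, 5.00, 3.44 and 6.06 RPKM at CT23, CT35, CT47 and CT59. The log2 difference of the first pair of phases minus the second was −1.12 (SE 0.14, adjusted p = 0.0459), and 1040 genes had an unadjusted p under 0.05. Sampling every 6 h sees a 12-h rhythm at 1 of its phases. At this spacing the term also takes up a 24-h rhythm that is not shaped as a cosine. Lcn2 stood highest at CT41 and CT65, which share a clock phase, so its call cannot tell such a shape from a 12-h rhythm. The Lcn2 call was also made by DESeq2 (adjusted p = 4.09e-06, among 16 genes) and by edgeR with TMM, chosen after seeing the data (0.0491). It was missed by edgeR with median-of-ratios factors (0.0523) and voom (0.0517), and after TMM rescaling (0.0726), after thinning (0.0767) and with the day as a block (0.123). It was kept without CT59 (0.0136), where 118 genes were called, and was lost without each of the other libraries (0.0889 to 0.378), where no gene was called.

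The second day was compared with the first to see whether expression drifted with time in darkness, which is joined here with pool and lane. No gene differed by limma, where 233 genes had an unadjusted p under 0.05 and the smallest adjusted p was 1. With edgeR 0 were called (216 at an unadjusted p under 0.05), with voom 0 (222) and with DESeq2 1 (120). Chance alone would bring a share of about 0.05 of the 11483 genes tested under that bound, and all of these counts lie lower. The lack of calls therefore does not exclude a drift. The gene called by DESeq2, named after its value was seen, was Cebpb, a transcription factor of liver metabolism and the acute phase, with a log2 difference of −2.0 (adjusted p = 1.03e-06). It shares 20.7% of its exon bases with Tmem189. It stood at 2.35, 13.8, 34.1 and 6.14 RPKM on the first day and at 1.65, 3.21, 3.90 and 1.58 RPKM on the second, and limma gave −1.75 (adjusted p = 1). The highest value, 34.1 RPKM, was that of CT35, the library that stood apart from the others. At the other phases the first day was also higher. Leaving out a library brought further calls, likewise named after their values were seen: 4 without CT23 and 5 without CT47, and 1 without CT35 or CT59. They were Cebpb (−2.20), Rpl38 (−1.40), 1700029I15Rik (1.16) and Gm9396 (1.35) without CT23 or CT47, Tnnc1 (−1.09) without CT47, and nonagouti (−1.25) without CT35 or CT59. With the clock phase as a block, leaving out either library of a same-phase pair removes that pair from the day comparison. Calls without CT23 and without CT47 are therefore not separate support, nor are those without CT35 and without CT59.

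Intron reads, which largely come from unspliced RNA, were compared with exons to set the timing of transcription beside that of the mature transcript. The exon peak followed the intron peak by 1.12 h for Dbp (8.03 to 9.15 h), 1.90 h for Per2 (12.80 to 14.70 h), 0.95 h for Arntl (20.68 to 21.63 h) and 1.64 h for Npas2. The lag was 2.22 h for Clock, 1.1 h for Cry1 and 1.02 h for Usp2. It was 0.10 h for Per1, 0.34 h for Nr1d1, 0.42 h for Nr1d2, 0.52 h for Per3 and 0.55 h for Tef. Bhlhe40 was called in introns (adjusted p = 0.00442) and not in exons (0.133), and Cry2 was called in neither (0.0913 in introns). The largest lags were those of Fmo5 (6.08 h, from 10.94 to 17.02 h), Cyp2a5 (4.26 h) and Crot, a carnitine acyltransferase of peroxisomes (3.85 h). The exon peak came first by the largest margin in Fbf1 (−2.13 h), Slc8b1 (−2.08 h) and Mbd1 (−1.64 h). The SE of the intron and exon peak times were 0.68 and 0.61 h for Fmo5, and 0.77 and 0.75 h for Clock. They were 0.6 and 0.76 h for Fbf1, 0.91 and 0.63 h for Slc8b1, and 0.82 and 0.66 h for Mbd1. For Per1 they were 0.51 and 0.69 h, larger than its lag. Lags of single genes were not tested, and those of Fmo5 to Mbd1 are extremes picked from all genes called in both.

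Of 6528 genes with enough intron reads, 308 had a 24-h component in introns by limma, and 971 had an unadjusted p under 0.05. Of 237 genes called in exons with intron values, 128 were called in both, so that 109 exon calls and 180 intron calls had no counterpart. Whether the rhythms of these genes differ between exons and introns was not tested. Among the 128 the exon peak was later in 102 and earlier in 26, with a median lag of 0.67 h (quartiles 0.16 and 1.43 h; 2-sided exact sign test across genes p = 7.78e-12). A permutation test by sign flipping gave p = 1e-05, the smallest it can give. Both treat genes as independent, which genes of the same pools are not, and in polyA-selected RNA introns held 7.87 to 13.8% of reads.

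**Figure D4:**
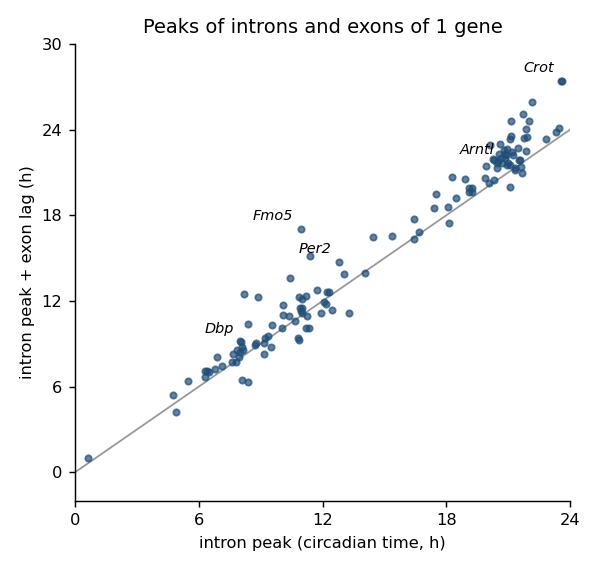
Intron peak time (horizontal axis, circadian time in hours) against the exon peak time (vertical axis, the intron peak plus the lag, in hours) of the 128 genes called in both; each point is a gene and the diagonal marks equal times. Most points lie above the diagonal (102 of 128), with Fmo5 farthest from it at a lag of 6.08 h.

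Splice site choice was examined in 1500 competing junctions of 778 genes, of which 1036 junctions belong to the transcript models. The smallest p-values were those of Wapl, a cohesin release factor (chromosome 14, 35505921 to 35508190, a mean share of 23.1% that ran from 17.5 to 30.2%, adjusted p = 0.165). Next, at an adjusted p of 0.412 each, came Habp4 (mean share 7.4%), Zfp207, Srrm2, a splicing factor, and Ces1b, a carboxylesterase with close paralogs. Upp2, a uridine phosphorylase, had a mean share of 93.7% (adjusted p = 0.925). The quasi-binomial test called 0 junctions, with 131 at an unadjusted p under 0.05, and limma on arcsine-transformed shares also called 0, with 126. Without CT23 there was 1 call, in Araf (chromosome X, 20435639 to 20435867, adjusted p = 0.0212), and without CT47 there was 1, in Cnbp (chromosome 6, 87795318 to 87795458, adjusted p = 0.00226), both named after their values were seen. In simulated shares a change of 1 on the log-odds scale was not recovered.

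The deepest library showed the most junctions. At least 1 read covered 123903 junctions in CT23, 125851 in CT29, 121633 in CT41, 127898 in CT47, 126464 in CT53, 125419 in CT59 and 121850 in CT65, from 5.27 to 6.23 M junction reads, and 159120 in CT35 from 14.7 M. After thinning to 5270743 junction reads each, the libraries had 118519 to 125851 junctions, with 123971 in CT35. Of 231440 junctions seen in any library 77572 were seen in all, 75686 of them in the transcript models.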

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

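Of the tests in this part, those of the clock phase and of the sequencing run for CT35, and those of the unshared exons of Thra and Sphk2, were chosen only after the result was seen.

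The CT35 library lay far from the other 7 in 8 of 12 measures compared over the 8 libraries, where chance places 1 library that far in about 1 of 20 sets. It had 22.9 M reads behind 1 RPKM, 508% of reads added by the upper estimate (153 to 316% in the others), 7.87% intron reads and 64.5 junction reads per 100 reads. It showed 159120 junctions, 19.7% of them absent from the transcript models (13.0 to 14.4% in the others), and 11.8% after thinning (12.8 to 13.7% in the others), so that the excess in this share went with depth. It had a residual SD of 0.284 around the 24-h curves (0.157 to 0.214 in the others) and a median correlation of 0.930.

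The tables argue against greater depth as the whole cause, because the residual SD of CT35 was still 1.34 times that of the next library after thinning to the shallowest, although its junctions then numbered 123971, inside the range of the others. They also argue against the GC content and length of genes, with a ratio of 1.31 after removal of those trends. Against the clock phase as the whole cause stands CT59, which shares it and correlated with CT35 at 0.9506. The other same-phase pairs correlated at 0.9784 to 0.9801. Yet 0.9506 lies above the median correlation of CT35 with the other libraries (0.9297), so a part played by the phase is left open. A different sequencing run or read length may lie behind the 64.47 junction reads per 100 reads, as longer reads cross more junctions. Its junction track line names no lane, unlike those of the other 7, but run and read length are not given in the sources used here, so this cannot be told apart from a difference between pools. No biological explanation beyond the clock phase was tested.

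Rhythms of genes that overlap or adjoin a rhythmic gene may come from its reads. For Thra the log2 peak to trough was 2.81 over the whole gene and 0.715 in exons that overlap no other gene (adjusted p = 0.45), and its last exon, beside Nr1d1, held 738 and 981 reads at CT29 and CT53 against 58 to 241 elsewhere. For Sphk2, beside Dbp, the values were 1.15 (adjusted p = 0.0273) and 0.381 (adjusted p = 0.643). For Pitx3, 0 spliced reads crossed the introns between its exons next to Elovl3. Its far exon (chromosome 19, 46222691 to 46222815) had 0 reads in all libraries. Both allow reads running on from Elovl3. In order of distance from Elovl3, its exons of 921, 203 and 130 bases held 82, 37 and 79 reads in CT23 and 114, 46 and 105 in CT47. Reads per base thus did not fall with distance. The introns of Pitx3 held a mean of 263.1 reads per library, with a log2 peak to trough of 6.01, against a mean of 85 reads in its exons. The source of the reads is left open, and Pitx3 is among the 128 genes whose intron and exon peaks were compared. Over the 49 of 61 called genes with shared exon bases that could be tested the tables argue against reads from the shared bases as a general cause. Unshared exons kept a median of 1.042 (SE 0.0291) of the whole gene's value, with 39 at 0.9 or more and 4 under 0.5 (Thra, Sphk2, Abi3 and Fpgs, named after their values were seen), and 25 of the 49 were called in their unshared exons. Pitx3 is among the 39 (ratio 1.191), so these ratios leave reads that run on past the shared bases open.

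A test of the day by rhythm term, which was not among the planned tests, called 3 genes, and 955 had an unadjusted p under 0.05. It left fewer residual degrees of freedom than the planned fits to all libraries. Gadd45g (adjusted p = 0.00593) stood at 20.8 RPKM in CT35 and at 1.58 to 5.24 RPKM elsewhere. Myc (adjusted p = 0.0171) stood at 13.0 RPKM in CT35 and at 2.02 to 6.74 RPKM elsewhere. Gadd45g and Myc thus stood out in the CT35 library alone, so a difference between the days cannot be told apart from one of that library. Gm11808 (adjusted p = 0.024) stood at 17.6 and 19.9 RPKM in CT29 and CT35 and at 36.8 to 91.4 RPKM elsewhere. Outside the junction usage test, 60 junctions absent from the transcript models had at least 20 reads in every library, and 2 of them joined paralogs, Serpina1c with Serpina1e (2104 reads) and Serpina1b with Serpina1e (901 reads).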

How the results depend on the processing

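The alternatives that are edgeR with TMM, TMM and equal-median scaling, removal of GC and length trends, array weights, and the lists and introns without CT35 were chosen after seeing the data. For single named genes, 6267 values under alternatives kept the direction of the 256 results given for them. Of these values 497 lost the call and 59 gained one, and 146 results held under all alternatives. Without a low-read filter, where many more genes are tested, 86 calls were lost. Leaving out 1 library lost from 20 (CT35) to 48 (CT53) calls, and these settings together held most of the losses. The day as a block is not a pairing of the labels and brought 268 calls for the 24-h component against 349. Counts that left 1.5 times the reported value were as follows, and the cause was not tested.

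For the 24-h component, DESeq2 called 768 genes, array weights 894 and no low-read filter 89, and leaving out 1 library gave 177 to 469. For CT23 against CT11 these were 486, 708 and 57, and 72 to 247 without 1 library, and for CT5 against CT17 they were 294, 245 and 33, and 47 to 311. For the 12-h component DESeq2 called 16 genes; 0 were called by edgeR with median-of-ratios factors, by voom, without a low-read filter, with the upper values, after thinning, with the day as a block, after TMM or equal-median scaling and after removal of GC and length trends, and 0 to 118 without 1 library. Between the days DESeq2 called 1 gene, and leaving out 1 library gave 0 to 5. Camera's 18 list calls fell to 0 with an estimated correlation and came to 25 without CT35, while 9 lists were enriched by Fisher's exact test, 9 with calls at an adjusted p under 0.01 and 10 without CT35. Junction usage gave 0 to 1 calls without 1 library. At a minimum of 5 reads, 59238, 62127, 91215, 58295, 64066, 62841, 62455 and 58172 junctions were detected from CT23 to CT65 in order of time.

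The other counts, and the median lag between introns and exons (0.67 to 0.81 h), stayed within 1.5 times. The high number of junctions in CT35 went with its depth, as 159120 fell to 123971 after thinning. Thinning changed the 24-h calls little, with 344 against 349. In simulations, which did not vary depth, 45.5% of genes with a 24-h log2 change of 1 were recovered.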

Other observations

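Of the tests in this part, that of the scaling behind the lag and those of other arrangements of the libraries were chosen only after the result was seen, and the genes of the first 2 paragraphs were chosen from the called genes after their values were seen.

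Of called genes outside the lists, which were not tested as groups, Chka, choline kinase, peaked at the end of the night (4.77-fold, log2 2.25, SE 0.20, 21.64 h, adjusted p = 0.000347) and Gpcpd1, which breaks down glycerophosphocholine, late in the day (9.89-fold, log2 3.31, SE 0.38, 8.89 h, adjusted p = 0.00164). Ppard, the nuclear receptor PPAR delta, peaked in the night (8.31-fold, log2 3.06, SE 0.35, 20.50 h, adjusted p = 0.00151), apart from Ppara at 9.66 h. Abcg5 and Abcg8, neighbouring genes whose products together export sterols, peaked at 8.26 h (4.0-fold, adjusted p = 0.00693) and 7.05 h (3.33-fold, adjusted p = 0.0095), and Insig2, which holds back sterol synthesis, at 0.42 h (3.47-fold, adjusted p = 0.00921). Crot, which passes fatty acids out of peroxisomes, peaked at 3.43 h (3.56-fold, adjusted p = 0.0013). The call of Abcg8 was lost without CT53 (adjusted p = 0.0524) and that of Insig2 without CT59 (0.0558), and the others were kept whichever library was left out.

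Slc7a2, a carrier of arginine and lysine, peaked at 8.31 h (4.68-fold, log2 2.23, SE 0.22, adjusted p = 0.000681) and Hdc, which makes histamine, at 7.73 h (3.56-fold, adjusted p = 0.00356), whereas Ddc, which makes dopamine and serotonin, peaked at 21.66 h (3.93-fold, adjusted p = 0.00211). Upp2, a uridine phosphorylase at a mean of 124.6 RPKM, peaked at 11.04 h (4.86-fold, adjusted p = 0.00128), and Noct, the Nocturnin gene, at 11.59 h (3.54-fold, adjusted p = 0.00536). Gabarapl1, a protein of autophagosomes, peaked at 5.39 h (3.35-fold, adjusted p = 0.00377). These 6 calls were kept whichever library was left out.

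Exon peaks that follow intron peaks may come from the time that mature transcripts take to build up. If turnover set the lag, genes whose exons had a smaller amplitude than their introns should lag more, but across the 128 genes the rank correlation of the amplitude ratio with the lag was −0.0723 (SE 0.0887, permutation p = 0.416), which leaves this open, also because the added 0.5 weighs differently on intron and exon amplitudes. Genes are not independent replicates. With introns and exons each scaled by TMM factors of their own reads, the median lag was 0.71 h (SE 0.0909). Introns and exons still had separate totals there, so this value cannot decide whether different scaling lies behind the lag. That value came from edgeR, so the test changed together with the scaling, and it covers the 153 genes called in both there. The tables argue against reads from shared exon bases, because the lag was 0.64 h (SE 0.102) among the 109 genes that share no exon base. No biological group of the design bears on the lag.

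Other arrangements of the libraries were tried for the counts of calls. Of 100 arrangements into pairs of the same phase, out of 315 possible, 1 gave as many 24-h calls as the real one, the real one itself. It gave 349 against 83 at most in the others, which argues against chance for the count of calls. Since 100 of the 315 were tried, 1 in 100 was the smallest share that could be found. For the 12-h component 14 of the 100 gave at least the 1 call of the real arrangement, so that chance cannot be excluded. The highest other count was 359, from an arrangement that sets CT41 and CT65 against CT29 and CT53 and so follows the 24-h phases, a structure of the samples. Between the days the real split gave 0 calls and the highest other 1, and the 8 splits that part every same-phase pair are too few for a share under 0.05.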
